A study of Mus musculus with 42 samples.

How the data were processed

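Macrophages of young and aged C57BL/6 mice were taken at 7 zeitgeber times, with 3 libraries per age and time and 42 libraries in all. Total RNA was extracted and made into 3' end libraries with a QuantSeq kit, per the labels' protocols. STAR, DESeq2 and the mouse genome build mm10 are named per the submitters' processing notes. The counter, the gene annotation and the versions of these tools are not given in the sources used here. The deposited values are a normalized signal per gene, which the authors made as 1 table for each age. Within a library every value above 0 is a whole multiple of the library's smallest value, as reads divided by a size factor are. Dividing by that step gave whole reads for 100.0% of the values, within a tolerance of 0.001 of a whole number. The implied size factors were between 0.769 and 1.43 in the young and between 0.592 and 1.84 in the aged table. The tables were normalized separately, so deposited levels are not on 1 scale across ages.

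Each table held 47643 genes, of which 47224 were matched to a symbol by Ensembl identifier and 22533 were at 0 in every library. Positions are those of GENCODE M21 on GRCm38, the build that mm10 names. Samples were grouped by age and time as the labels give them. Recovered reads per library were between 7433159 and 13574542 in young and between 4864402 and 15587030 in aged cells. Genes of the mitochondrial genome took 1.39% to 1.88% and 1.35% to 2.27% of the reads, and the top 10 genes 12.2% to 15.8% and 12.9% to 18.0%. Reads without molecular identifiers are not independent molecules, and 3' end counting rests on the annotated end of each gene. All 42 pairs of replicates differed by more than sampling noise, with a chi-square per gene of 7.82 to 59.14, so no library was taken as a copy of another.

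Rhythms were tested within each table. Values were put on the scale log2(value + 1), genes with a mean of at least 10 were kept, and limma-trend (limma 3.58.1 in R 4.3.3) fitted a cosine and a sine of 24 h with a moderated F-test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The median SD between libraries of a group was 0.268 in young and 0.309 in aged cells on this scale, and 66.3% of genes had the larger SD in aged cells. For comparisons across ages the recovered reads of all 42 libraries were rescaled together by the median of ratios. The difference in rhythm was tested by the age by cosine and age by sine terms, and the mean level over the day, and the level at each time, by contrasts in a model with 14 group means. Fold changes on this scale understate the change of genes with few reads. The median log2 fold over all genes was 0.00. The peak-to-trough fold is that of the fitted cosine. The 43 gene lists, fixed before the data were examined, as were the tests, the main settings and the rule for named genes, were tested as mean profiles with limma and for level with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Of these lists 42 could be tested for level.

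Genes named in the text follow a fixed rule. For rhythms these are the 12 genes of the widest amplitude among those called, for the difference in rhythm the 12 lowest p-values, and for level the 10 largest rises and falls among called genes with the same sign at all 7 times. Gene models without a symbol, Gm and Rik names, immunoglobulin and T cell receptor segments and pseudogenes are passed over in these. From the lists come all measured clock genes, Klf4 and up to 4 members of lowest p of each other list, and for single times and for ZT24 against ZT0 up to 3 genes of lowest p. The text names some of them, and 1 of the largest rises is not reported here.

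EdgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives. EdgeR called 467 genes rhythmic in young cells, 36 in aged cells and 2873 different in level, and DESeq2 737, 91 and 3051, where the adjusted p of 2114 genes was missing in the young test. Other alternatives were the pseudocount, the filter, the scaling, the model of time, the threshold, covariates for B, T and mast cell markers, and each library left out. Limma array weights and a fit without the 2 aged libraries farthest from their groups were added after the data had been seen. Tests across genes were checked on simulated data with 200 changed genes, drawn gene by gene without deviations that a library shares across genes. At a log2 size of 1 they recovered 90.9% of rhythms in young and 89.4% in aged cells, 84.8% of differences in rhythm, 95.5% of level changes, 45.5% of changes at 1 time and 59.1% of changes between ZT24 and ZT0. At a log2 size of 0.5 these were 65.7%, 53.7%, 52.2%, 64.2%, 7.46% and 11.9%, and at 0.25 they were 17.9%, 19.4%, 7.46%, 35.8%, 0% and 1.49%. For rhythms the size is the amplitude of the cosine, from mean to peak. Unchanged genes made up 1.69% of the calls for young rhythms, 6.09% for aged rhythms and 3.03% for differences in rhythm. Their share was 4.41% for level, 0% at 1 time and 9.43% for ZT24 against ZT0. Python 3.11.15 with pandas 2.3.3 read the tables.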

Results

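RNA of macrophages from young (2 to 3 months) and aged (18 to 20 months) C57BL/6 mice was sequenced over the day. The labels do not name the tissue the macrophages came from. Cells were taken at 7 zeitgeber times (ZT, hours on the light cycle of the animal house), from ZT0 to ZT24 in steps of 4 h. Each of the 14 groups of 1 age and 1 time held 3 libraries, which makes 21 libraries per age and 42 in all. The libraries are of a 3' end kind, in which a read marks the end of a transcript and gene length does not enter the value. The young libraries held 7433159 to 13574542 reads in genes (median 9847012) and the aged libraries 4864402 to 15587030 (median 8159784). Between 14576 and 16941 genes were above 0 in a young library and between 14457 and 16988 in an aged one. The labels do not say that the libraries of a group are separate animals, so the p-values measure the spread between these samples, which may be technical.

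The first comparison asked which transcripts follow a 24 h rhythm in young macrophages. The widest fitted amplitudes were those of the circadian clock genes Nr1d1, Per2 and Dbp. Nr1d1, a repressor of the clock (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333, minus strand, build GRCm38), rose from 2.37 ± 4.10 (SD, n = 3) at ZT0 to 209 ± 37.9 (SD, n = 3) at ZT8 in rescaled reads. Arntl, which Nr1d1 represses and which encodes the activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, plus strand), ran in the opposite phase, from 291 ± 33.2 (SD, n = 3) at ZT0 to 64.4 ± 6.88 (SD, n = 3) at ZT12. Dbp, a transcription factor driven by the clock (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203, minus strand), peaked at ZT 12.9 ± 0.320 (SE) with a fitted peak-to-trough fold of 19.8. The repressor gene Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324, minus strand) peaked at ZT 17.3 ± 0.382 (SE) with a fold of 26.9. Of the 16 measured genes of the clock list, 12 were rhythmic over all genes and 13 adjusted over the list alone. Clock, Bhlhe40, Bhlhe41 and Rora were not called over all genes. Limma's moderated F-test with Benjamini-Hochberg adjustment called 438 of 12113 genes rhythmic in young macrophages, with adjusted p = 6.10e-15 for Nr1d2 and 4.48e-14 for Tef. At an unadjusted p under 0.05 there were 2082 genes, against 606 by chance. The median peak-to-trough fold of the called genes was 1.54. Fitted peaks fell in every part of the day, most often between ZT20 and ZT24 (106 genes) and least often between ZT0 and ZT4 (54).

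**Figure D1:**
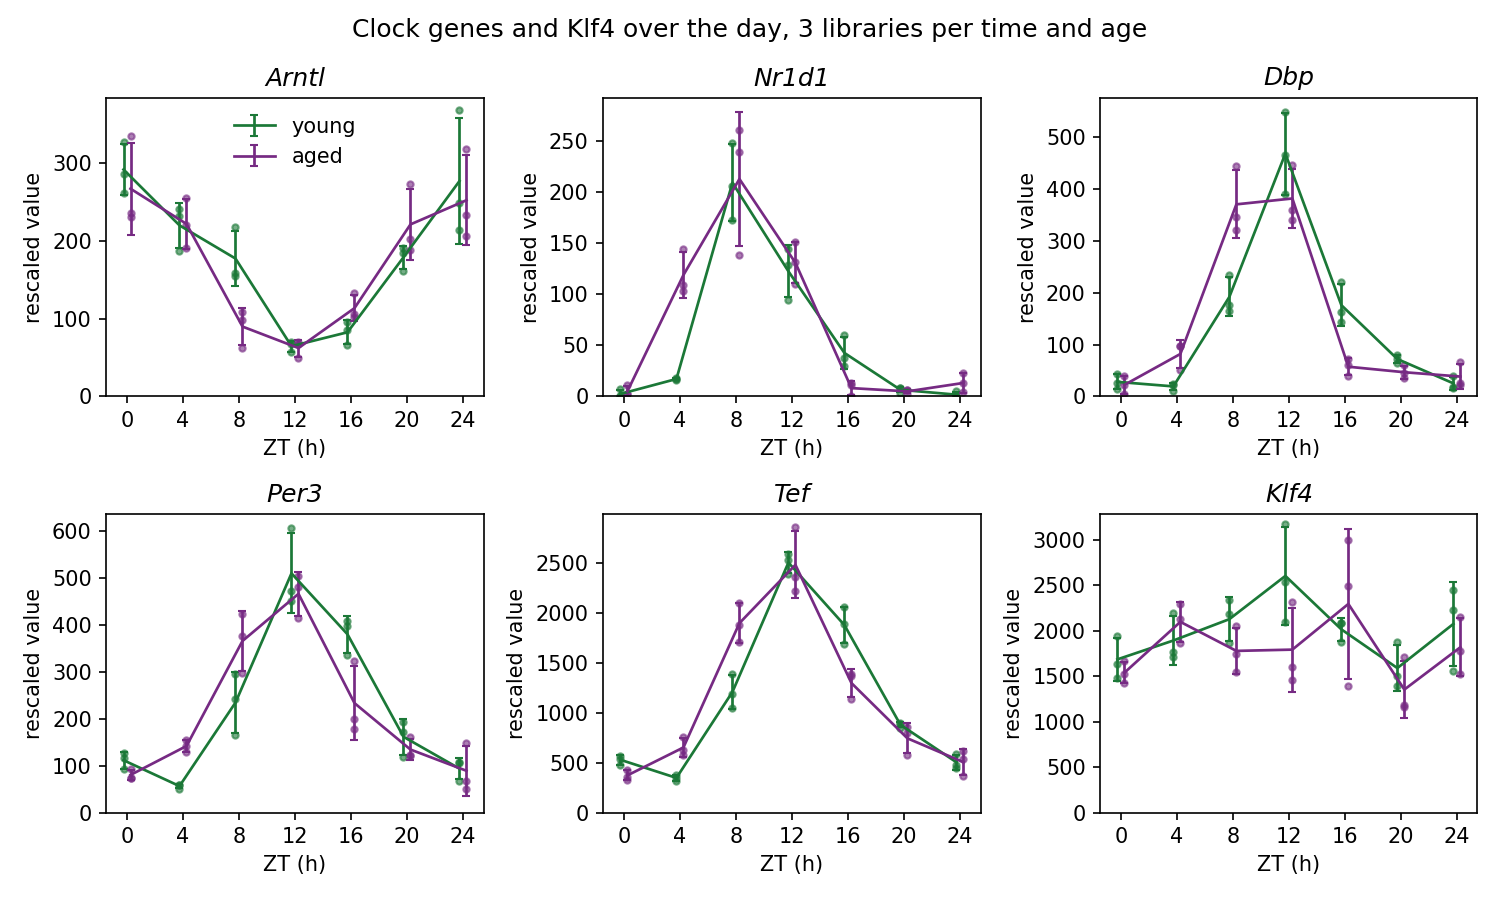
Rescaled reads of Arntl, Nr1d1, Dbp, Per3, Tef and Klf4 against zeitgeber time in hours, with a point per library and a line through the mean of 3 libraries ± SD, in green for young and in purple for aged macrophages. Dbp reached 468 ± 79.1 at ZT12 in young cells, and 370.4 ± 65.6 at ZT8 and 382 ± 56.2 at ZT12 in aged cells (SD, n = 3).

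Genes of protein folding cycled together in young macrophages. Of 19 measured heat shock genes, many of which encode chaperones, 11 were rhythmic over all genes and 17 adjusted over the list alone. Hsph1 had a peak-to-trough fold of 4.09 around ZT 20.2 ± 0.541 (SE) and Stip1 one of 1.93. Hspa1a and Hspa1b, near-identical copies whose reads may be split between them, peaked at ZT 21.8 and 21.5. Of 24 genes of protein folding in the endoplasmic reticulum, 13 were rhythmic over all genes and 19 adjusted over the list alone, among them Hspa5 (fold 1.77), Hsp90b1 (1.44) and Pdia6 (1.5). The mean profile of the heat shock list peaked at ZT 21.05 ± 0.794 (SE) with a fold of 1.85 (limma, adjusted p = 0.00355), and that of the endoplasmic reticulum list at ZT 21.4 ± 0.701 with a fold of 1.35 (limma, adjusted p = 0.00115). Cirbp, an RNA-binding protein gene induced by cold, ran against them, with a peak at ZT 7.87 ± 0.702 (SE) and a fold of 3.54 (limma, adjusted p = 0.00641). Hspa1b lost its call without the ZT0 libraries, at an adjusted p of 0.0543 by limma.

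Genes that respond to glucocorticoids peaked near the middle of the sampled day in young macrophages. Of 15 measured members, 5 were rhythmic over all genes and 8 adjusted over the list alone. Fkbp5, a co-chaperone of the glucocorticoid receptor, had a fold of 6.00 with a peak at ZT 13.9 ± 0.497 (SE). Klf9 (fold 2.42), Tsc22d3 (2.79) and Ddit4 (2.74) peaked at ZT 13.3, 15.9 and 14.5. The mean profile of the list peaked at ZT 14.9 ± 0.632 (SE) with a fold of 1.60 (limma, adjusted p = 0.000577).

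Some genes of lipid handling, uptake and chemoattraction also cycled in young macrophages, while the mean profiles of their lists were not called. Lpl, which encodes lipoprotein lipase, had a fold of 3.20 with a peak at ZT 4.50 ± 0.425 (SE), and the lipid droplet gene Plin2 one of 2.19 at ZT 1.90. Abcg1, a cholesterol exporter gene, peaked at ZT 16.9 with a fold of 2.07. In the lipid efflux list 6 of 17 members were rhythmic over all genes and 7 adjusted over the list alone. In the list of phagocytosis receptors and opsonins 7 of 27 were rhythmic over all genes and 10 adjusted over the list alone, among them Timd4 (fold 1.54, ZT 2.48) and Fcgr2b (1.41, ZT 16.9). The chemokine gene Cxcl13 had a fold of 2.70 at ZT 21.04, and 5 of 23 inflammatory cytokine and chemokine genes were rhythmic, also 5 adjusted over the list alone. The limma adjusted p of the mean profile was 0.322 for lipid efflux, 0.673 for phagocytosis receptors and 0.489 for cytokines and chemokines. The mean profile of the resident macrophage list, which holds Cxcl13 and Timd4, peaked at ZT 23.2 ± 0.869 (SE; limma, adjusted p = 0.00355). That of the list of monocyte-derived macrophages peaked at ZT 11.6 ± 0.995 (SE; adjusted p = 0.00862). This profile lost its call with upper quartile scaling (0.0510) and with 7 time levels (0.135). Klf4, a transcription factor gene of macrophages, had a fitted fold of 1.38 in young cells and was not called (limma, adjusted p = 0.0710), nor in aged cells (fold 1.22, adjusted p = 0.793). Its adjusted p in young cells was 0.0444 without ZT8 replicate 3, 0.0363 without ZT24 replicate 1, 0.0186 without ZT24 replicate 3 and 0.00793 without the ZT24 libraries.

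Other genes of wide amplitude in young macrophages had calls that leaving out 1 library ended. Ciart, a clock repressor gene at a mean of 13.3 reads, had a fold of 9.78 and limma adjusted p = 0.0174, which became 0.0556 to 0.0649 without ZT12 replicates 1, 2 and 3, and 0.152 without the ZT0 libraries. Cry2, a clock repressor gene with a fold of 2.02, had adjusted p = 0.0333, which became 0.0546 to 0.0784 without ZT4 replicates 1, 2 and 3, ZT12 replicates 1, 2 and 3 or ZT16 replicate 1, and 0.0558 without the ZT24 libraries. The zinc finger gene Zfp811 (fold 7.42, adjusted p = 0.0401) moved to 0.0514 to 0.10 without ZT0 replicate 2, ZT8 replicate 3, ZT12 replicate 2, ZT20 replicate 3 or ZT24 replicates 1, 2 and 3, to 0.0931 without the ZT0 libraries and to 0.183 without the ZT24 libraries. The growth factor gene Igf2 (fold 5.72, adjusted p = 0.0480) moved to 0.0505 to 0.125 without ZT0 replicates 1 and 2, ZT4 replicates 1 and 2, ZT8 replicates 1, 2 and 3, ZT12 replicates 2 and 3, ZT16 replicates 1 and 2, ZT20 replicate 1 or ZT24 replicates 1 and 3, to 0.0860 without the ZT0 libraries and to 0.145 without the ZT24 libraries.

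In aged macrophages the widest fitted amplitudes were again those of the clock genes Nr1d1, Dbp and Per2. Of 16 measured clock genes 10 were rhythmic over all genes and 13 adjusted over the list alone. Nr1d1 had a fold of 84.0, Dbp of 16.7, Per2 of 6.39 and Tef of 5.64. Klf9 (fold 2.71), Tsc22d3 (2.16) and the inflammasome gene Nlrp3 (2.99, peak at ZT 22.3 ± 0.507, SE) were called as well. Of 20 heat shock genes 2 were called over all genes and 13 adjusted over the list alone, and the mean profile of that list peaked at ZT 20.4 ± 0.765 (SE) with a fold of 1.48 (limma, adjusted p = 0.00925). Limma called 37 of 12016 genes rhythmic in aged macrophages, with adjusted p = 3.03e-10 for Tef and 3.50e-07 for Arntl, and 1083 at an unadjusted p under 0.05, against 601 by chance. The median fold of the called genes was 2.24. In the lists of endoplasmic reticulum folding, lipid efflux and phagocytosis receptors limma called 0 genes in aged cells over all genes, and 0, 2 and 0 adjusted over the list alone. Fkbp5 (limma adjusted p = 0.0386) moved to 0.0578 to 0.158 without aged ZT0 replicates 1, 2 and 3, ZT4 replicates 1, 2 and 3, ZT8 replicates 1 and 2, ZT12 replicates 1, 2 and 3, ZT20 replicate 3 or ZT24 replicates 2 and 3, and to 0.327 without the ZT0 libraries. Hsph1 (0.0302) moved to 0.0526 to 0.120 without aged ZT4 replicates 1, 2 and 3, ZT8 replicates 1, 2 and 3, ZT16 replicate 2 or ZT20 replicate 3, and to 0.0774 without the ZT24 libraries.

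The next comparison set the rhythms of the ages side by side. Clock genes peaked earlier in the aged libraries: all 10 clock genes called in both ages did so, with a mean shift of -2.48 h. Each age has a table of its own, so a harvest or light schedule that goes with age cannot be told apart from age here. Nr1d1 peaked at ZT 10.8 ± 0.356 (SE) in young and at ZT 8.03 ± 0.379 in aged cells, Dbp at ZT 12.9 ± 0.320 and 10.03 ± 0.433, and Tef at ZT 13.7 ± 0.227 and 11.7 ± 0.267. Arntl peaked at ZT 1.53 ± 0.365 in young and at ZT 23.6 ± 0.382, late in the cycle before, in aged cells. The shift of aged minus young was between -3.54 h (Cry2) and -1.71 h (Nr1d2), with an exact sign-flip p of 0.00195 over the 1024 flips (two-sided, 10 genes, which are not independent of each other). That is the smallest value these flips can give, and any offset common to the genes would reach it. The mean profile of the clock list peaked at ZT 13.7 ± 0.299 (SE) in young and ZT 10.9 ± 0.375 in aged cells. Of 42 list profiles tested for a difference in rhythm between ages it was the only one called by limma (adjusted p = 0.000448). The call of Cry1 in aged cells (limma, adjusted p = 0.00574) was lost with 7 time levels (0.107) and with a linear drift term (0.0694). The fitted amplitude in aged cells was 46.2% of that in young cells for Cry1, 56.3% for Per2 and 70.6% for Nr1d2, and 89.9% to 138% for the other 7 genes. Over the 10 genes, which are not independent, the mean log2 amplitude ratio was -0.22, with an exact two-sided sign-flip p of 0.152. Clock genes called in young but not in aged cells are left out of it, so it may miss losses of amplitude.

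**Figure D2:**
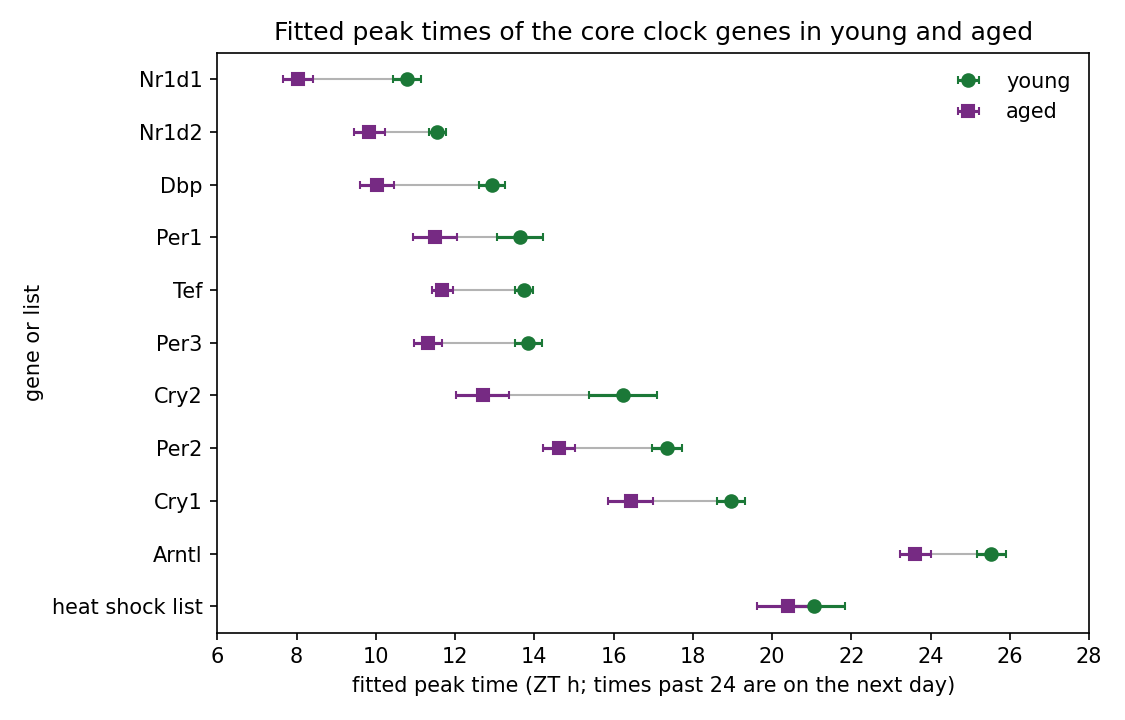
Fitted peak time in hours of zeitgeber time, ± SE, of 10 clock genes and of the mean profile of the heat shock list in young (green) and aged (purple) macrophages, each from 21 libraries, with times past 24 on the next day. The 10 clock genes peaked earlier in aged cells, and the heat shock profile peaked at ZT 21.05 ± 0.794 in young and ZT 20.4 ± 0.765 in aged cells.

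The genes called rhythmic overlapped between the ages. Of 11782 genes tested in both, 31 were called in both, where independent lists would share 1.38 (Fisher's exact test, one-sided p = 3.16e-39). That test takes genes as independent, which genes of the same libraries are not, so its p does not measure the spread between libraries. Of the 438 genes called in young cells 178 had an unadjusted p under 0.05 in aged cells. A smaller amplitude in aged cells was fitted for 364 of them, a count that selection on the young libraries inflates. The test of the difference itself, limma's F-test of the age by rhythm terms over 12080 genes, called 0 genes, with a lowest adjusted p of 0.0516, shared by Tef, Cry1, Gbp8, Nr1d2 and Adamtsl5. At an unadjusted p under 0.05 it gave 494 genes, against 604 by chance, while edgeR called 4 and DESeq2 7. Adjusted over the clock list alone 9 of 16 genes differed, and adjusted over the 444 genes called in either age 9 did. The latter genes were picked by their rhythm in the same libraries, which widens the fitted difference between ages, so that count is not independent evidence. Genes called in young cells alone, Adamtsl5 among them, are not shown to differ between ages. The count of 0 became 1 without young ZT4 replicate 3, ZT8 replicate 1, ZT20 replicate 2 or ZT20 replicate 3 or aged ZT24 replicate 1, 2 without aged ZT4 replicate 2, 3 without young ZT8 replicate 2, young ZT12 replicate 2 or aged ZT24 replicate 3, 4 without aged ZT20 replicate 2 or without the ZT0 libraries, and 5 without aged ZT0 replicate 2 or aged ZT12 replicate 1.

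The third comparison asked which genes differ in mean level over the day between ages. For this the reads of all 42 libraries were rescaled together, since the 2 tables had been normalized separately. Each age has a table of its own, so a batch of harvest or sequencing that goes with age cannot be told apart from age. Transcripts of Cxcl13 were higher in aged macrophages. The gene encodes a chemokine that attracts B cells (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068, plus strand) and rose from 3000.4 ± 1259 (SD, n = 21) to 18135 ± 7441 (SD, n = 21) rescaled reads, a log2 fold of 2.59 ± 0.10 (SE). The acute phase gene Saa3, which has close copies, rose by 1.70 ± 0.17 on the log2 scale and Lrg1 by 1.44 ± 0.13. The complement genes C3 (1.38 ± 0.08), Cfb (1.53 ± 0.13) and C4b (0.74 ± 0.09) rose too, and of 13 measured complement genes 5 rose and 4 fell (6 and 5 adjusted over the list alone), a list that camera did not call (adjusted p = 0.0984). Limma called 2862 of 12080 genes, 1446 higher and 1416 lower in aged cells, of which 274 and 250 changed at least 2-fold. The split moved with the scaling, to 1441 higher and 1146 lower with upper quartile scaling and 1275 and 1646 with scaling to the total. The adjusted p was 1.03e-21 for Cxcl13 and 6.79e-16 for C3 (limma, Benjamini-Hochberg). Among genes with the same sign at all 7 times, the widest rises included those of Chit1, a chitinase gene of activated macrophages (1.45 to 87.7 rescaled reads), Nexmif, Prss35, Wipf3, Adgrl2, Loxl2, Trim43a, Gzmk and Dcn, with log2 folds of 3.35 to 4.91. With scores of B, T and mast cell markers as covariates 1414 genes were called in place of 2862, of which 1174 were among the 2862. For those 2862 genes the median absolute log2 fold went from 0.38 to 0.34 and the median SE from 0.0921 to 0.132, and 96.2% kept their sign.

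Among the fixed lists, camera called 13 of 42 at its preset correlation of 0.01, 8 higher and 5 lower in aged macrophages, and 0 with an estimated correlation (12 at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, called 30. Of 37 interferon-stimulated genes 18 rose and 1 fell (19 and 1 adjusted over the list alone), such as Rsad2 (0.83 ± 0.18), Irf7 (0.61 ± 0.14) and Ifi44 (2.87 ± 0.37, log2 ± SE). Of 13 genes of antigen presentation on class I molecules 7 rose and 0 fell by limma (9 and 0 adjusted over the list alone), such as H2-K1 (0.56 ± 0.07), B2m (0.35 ± 0.07) and H2-Q7 (0.96 ± 0.12), where close copies of class I genes may share reads. Of 19 resident macrophage genes 10 rose and 2 fell (10 and 3 adjusted over the list alone), with Cxcl13, Lrg1 and Saa3 among the rises. Of 24 inflammatory cytokine and chemokine genes 5 rose and 2 fell, over all genes and adjusted over the list alone. Its rises were led by Cxcl13, Ccl5 (1.80 ± 0.20) and Il10 (2.37 ± 0.33), which encodes a cytokine that damps inflammation. Camera gave the interferon list an adjusted p of 0.000211, with adjusted p = 0.390 with an estimated correlation. The values were 1.06e-05 for the class I list (adjusted p = 0.162 with an estimated correlation), 0.000202 for the resident list (adjusted p = 0.219 with an estimated correlation) and 0.0307 for the cytokine list (adjusted p = 0.162 with an estimated correlation). The cytokine list lost its call without aged ZT16 replicate 1 (0.0707) and without aged ZT24 replicate 3 (0.0546). At a filter of 50 it had 0.0611. The same aged libraries held more of the B cell markers (median log2 fold 0.59) and of the T cell markers (0.72).

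Genes of cell division were lower in aged macrophages. All 24 measured proliferation genes fell, over all genes and adjusted over the list alone, with a median log2 fold of -1.11. Birc5, a gene of dividing cells, fell from 983 to 351 rescaled reads (log2 fold -1.63 ± 0.20, SE), and the replication genes Mcm5 (-1.08 ± 0.12), Mcm3 (-0.72 ± 0.09) and Mcm6 (-0.68 ± 0.08) fell with it. Of 15 genes of monocyte-derived macrophages 10 fell and 2 rose, also adjusted over the list alone. They included Ccr2, the receptor that draws monocytes into tissue (-0.92 ± 0.11), Retnla (-1.05 ± 0.13), Fcrls (-1.46 ± 0.13) and Mgl2 (-1.37 ± 0.17). Of 20 heat shock genes 11 fell and 0 rose by limma (13 and 0 adjusted over the list alone), with Hsp90aa1 at -0.42 ± 0.07, and Cirbp rose by 0.87 ± 0.12. Of 72 nuclear genes of oxidative phosphorylation 23 fell and 0 rose (24 and 1 adjusted over the list alone), by a small amount (median log2 fold -0.11). Lpl fell as well (-1.43 ± 0.11), and the widest falls with the same sign at all 7 times were of Apoc1 (164 to 13.2 rescaled reads), Shank3, Akr1c18, Sv2b, Lyve1, Ccr3, Asz1, Adgrf5, Lmo1 and Cd209g, with log2 folds of -4.04 to -2.17. Camera gave adjusted p = 4.60e-24 for proliferation, 2.36e-06 for monocyte-derived macrophages and 0.000172 for heat shock, and for each of these 3 adjusted p = 0.162 with an estimated correlation. For oxidative phosphorylation it gave 1.06e-05, and adjusted p = 0.219 with an estimated correlation. In the same aged libraries the markers of dendritic cells were lower (median log2 fold -0.63) and those of B and T cells higher (0.59 and 0.72).

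**Figure D3:**
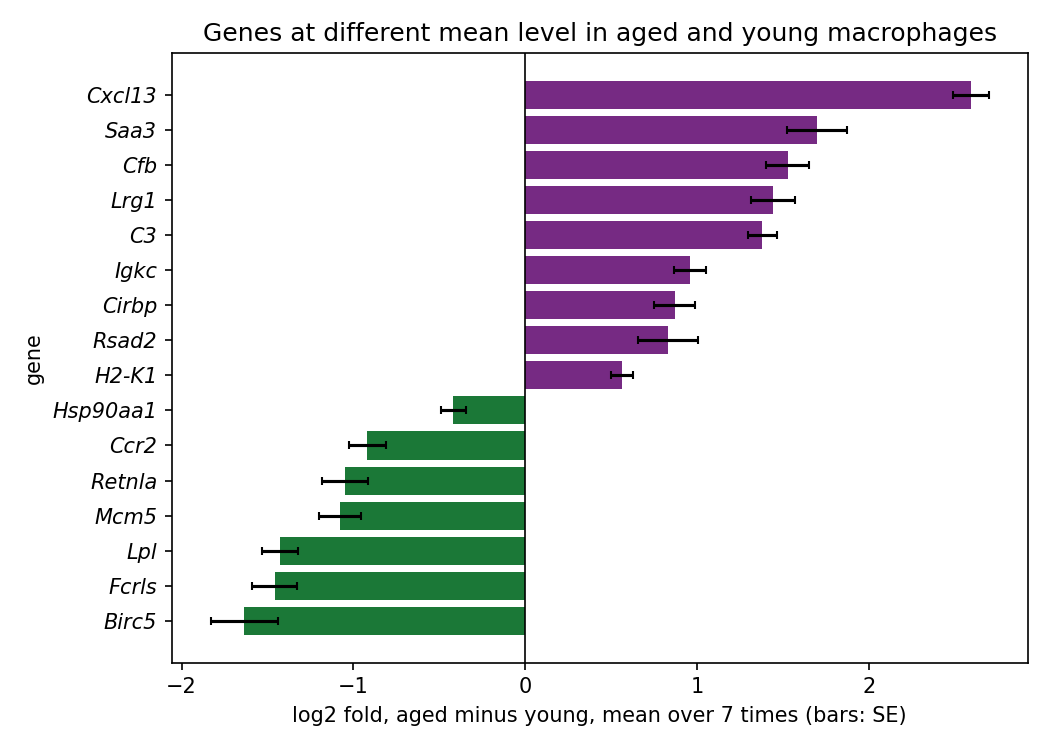
Log2 fold of aged over young macrophages, as the mean over 7 times, for 16 genes, with bars for the SE and colours for the direction (purple higher, green lower in aged). The folds were between -1.63 for Birc5 and 2.59 for Cxcl13, from 21 libraries per age.

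Markers of other cell types moved with age in the same libraries. Of 15 B cell markers 12 rose and 0 fell by limma, also adjusted over the list alone, with Igkc at 3427 ± 562 (SD, n = 21) in young and 6909 ± 2189 (SD, n = 21) in aged cells and Ighd at a log2 fold of 1.3 ± 0.14 (SE). Of 14 T cell markers 6 rose and 0 fell (7 and 0 adjusted over the list alone), such as Cd8b1 (11.2 to 40.4 rescaled reads). Of 4 natural killer cell markers 3 rose, also adjusted over the list alone, among them Nkg7 and Ccl5, the latter a member of the cytokine list too. Of 13 listed mesothelial or fibroblast markers 4 passed the filter over all 42 libraries, against 1 in young and 5 in aged libraries alone. Such a filter favours genes that are high in 1 age. Of the 4, 3 rose, also adjusted over the list alone: Dcn (4.44 to 39.6 rescaled reads), Krt18 and Krt8. Of 6 dendritic cell markers 4 fell and 0 rose by limma, also adjusted over the list alone, with Cd209a at -1.20 ± 0.11 and Batf3 at -0.85 ± 0.12. Of 9 mast cell markers 1 rose and 1 fell (1 and 2 adjusted over the list alone), and camera did not call the list (direction down, adjusted p = 0.997), whose median log2 fold was -0.14 and mean 0.06. Of 5 plasma cell markers 3 rose and 1 fell (4 and 1 adjusted over the list alone). Of 3 eosinophil markers, a list that holds Ccr3, 1 rose and 2 fell, with a median log2 fold of -1.22. Of 5 neutrophil markers 1 rose and 2 fell, and of 4 erythroid markers 1 fell and 0 rose. Camera called none of these lists (adjusted p = 0.102, 0.197, 0.496 and 0.127). Of 13 macrophage markers 6 fell and 0 rose, also adjusted over the list alone, with C1qa at -0.23 ± 0.06 on the log2 scale, and camera did not call the list (adjusted p = 0.0595). That value fell to between 0.0297 and 0.0492 without young ZT0 replicate 1, ZT4 replicate 1, ZT12 replicate 3, ZT16 replicate 3 or ZT20 replicate 3 or aged ZT0 replicate 2, ZT4 replicates 1 and 2, ZT8 replicates 1 and 3, ZT12 replicate 2 or ZT24 replicate 1. Camera gave adjusted p = 1.88e-09 for B cells, 0.00850 for natural killer cells, 0.00627 for mesothelial cells or fibroblasts and 0.00193 for dendritic cells, and for each of these 4 adjusted p = 0.162 with an estimated correlation. For T cells it gave 0.0109, and adjusted p = 0.382 with an estimated correlation. The natural killer list lost its call without aged ZT4 replicate 3 (0.0576) and without aged ZT12 replicate 1 (0.0546). It had 0.156 at a filter of 1 and 0.134 with no filter, and the T cell list had 0.111 at a filter of 50.

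At single times 3 libraries stood against 3. Cxcl13 was higher in aged cells at each time, with log2 folds of 2.39 at ZT0, 2.28 at ZT8, 2.54 at ZT16 and 2.31 at ZT24. Lpl was lower at ZT8 (-2.57), the hypoxia gene Egln3 higher at ZT12 (2.11) and C3 higher at ZT4 (1.74) and ZT16 (2.31). Ide, which encodes a protease of insulin, was lower at ZT20 (736 ± 93.1 and 366 ± 17.2 rescaled reads in young and aged cells, SD, n = 3). At ZT0 limma called 60 genes higher and 36 lower in aged cells, in all 96, against 53, 47 and 63 without young replicates 1, 2 and 3 and 48 and 51 without aged replicates 1 and 3. The numbers at ZT4 were 82 and 81, in all 163, against 73 and 78 without young replicates 2 and 3 and 76 and 80 without aged replicates 1 and 3. At ZT8 they were 238 and 246, in all 484, against 244 and 147 without young replicates 2 and 3 and 210 and 305 without aged replicates 1 and 2. ZT12 gave 147 and 104, in all 251, against 130 and 119 without young replicates 1 and 2 and 103 without aged replicate 3. ZT16 gave 94 and 34, in all 128, against 55, 67 and 75 without young replicates 1, 2 and 3 and 193 and 63 without aged replicates 1 and 3. ZT20 gave 127 and 73, in all 200, against 59 and 63 without young replicates 1 and 2 and 33 and 100 without aged replicates 1 and 2. ZT24 gave 132 and 121, in all 253, against 120, 108 and 150 without young replicates 1, 2 and 3 and 32, 87 and 452 without aged replicates 1, 2 and 3. Upper quartile scaling moved the higher and lower counts to 43 and 115 at ZT4, 117 and 31 at ZT20 and 151 and 69 at ZT24, and scaling to the total gave 63 and 120 at ZT4. In data simulated at this size a 2-fold change at 1 time was recovered for 45.5% of genes, so the counts give no order of the times.

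The ends of the sampled day were compared within each age, since ZT0 and ZT24 are the same phase of the light cycle. No gene passed in either age by limma. In young cells the lowest adjusted p was 0.188, for Zfp319, at a log2 fold of ZT24 over ZT0 of 2.61 ± 0.51 (SE). The fatty acid oxidation gene Cpt1a stood at -0.71 ± 0.16. In aged cells the lowest adjusted p was 0.9998, with the interferon-induced Slfn5 at -0.92 ± 0.23. Limma called 0 genes in young and 0 in aged cells, against 555 and 420 at an unadjusted p under 0.05. EdgeR called 0 and 0, and DESeq2 1 and 0. Without young ZT0 replicate 3 limma called 2 genes in young cells, Zfp319 and Cpt1a, each at an adjusted p of 0.0144. In simulated young data 59.1% of 2-fold changes between ZT24 and ZT0 were recovered, so smaller ones were mostly not detectable at this size.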

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

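The tests of a common offset and of random assignment of libraries to ages were chosen only after the earlier clock had been seen. The rhythm of the clock list differed between the ages by a test of the difference itself. Its mean profile differed by limma at an adjusted p of 0.000448, and the 10 clock genes had a mean shift of -2.48 h, earlier in aged cells. Over all 12080 genes limma called 0 differences in rhythm, with a lowest adjusted p of 0.0516 and 494 genes at an unadjusted p under 0.05, while edgeR called 4 and DESeq2 7. Adjusted over the 444 genes called in either age, limma gave 0.00237 for Tef, Cry1, Nr1d2 and Adamtsl5, 0.00344 for Nr1d1, 0.00395 for Dbp, 0.00511 for Per3 and Per2 and 0.0343 for Bccip. These 444 genes were picked by their rhythm in the same libraries, which widens the fitted difference, so the values do not show on their own that a gene differs. Bccip lies outside the rule for named genes and was chosen after its values were seen. Adamtsl5 had a fitted fold of 1.83 with a peak at ZT 17.3 in young cells, and was not called in aged cells (limma, adjusted p = 0.620). Its call in young cells (0.00850) was lost with 7 time levels (0.0725) and with a linear drift term (0.0599).

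For the earlier clock, a wrong time for 1 aged time point is argued against, since leaving out any 1 of them left a mean shift of -2.06 h or further from 0, and so is a random assignment of libraries to ages, with a permutation p of 1e-05, the smallest that 100000 shuffles can give. One offset of every rhythm, as from another harvest time or light schedule, was weighed with the other 426 genes called in young cells. Their common shift was -0.588 h, against -2.53 h for the clock genes. The 95% intervals were -1.32 to 0.156 and -2.85 to -2.21 with libraries drawn within groups. With residuals of libraries drawn they were -1.46 to 0.325 and -3.09 to -1.93. The sets were chosen unlike, the clock genes by calls in both ages and the others by young cells alone. Of all 438 genes called in young cells, 178 had an unadjusted p under 0.05 in aged cells (limma). The values argue against a common offset for the other genes as a set, and not for single genes. Smaller groups did not decide it. The heat shock genes, at -0.642 h, had an interval of -1.41 to 0.245 with libraries drawn within groups, which excludes -2.53 h. With residuals drawn it was -2.59 to 1.48, which does not. Profiles called in young cells alone had fitted shifts of -3.30 h ± 1.80 (SE) for glucocorticoid response and -2.31 h ± 1.87 for cold-inducible genes. Shifts were -0.802 h ± 1.42 for endoplasmic reticulum folding and -0.400 h ± 2.62 for resident macrophages. They were -0.861 h ± 2.32 for senescence and 1.06 h ± 3.88 for monocyte-derived macrophages. The call of the senescence profile in young cells (limma, adjusted p = 0.0469) was lost without 1 of many young libraries (0.0516 to 0.105). Without the ZT24 libraries it was lost too (0.152). The glucocorticoid profile was called in aged cells without aged ZT24 replicate 1 (limma, adjusted p = 0.00570) and without the ZT24 libraries (0.0180). A schedule that moved the clock and the genes it drives but not other rhythms stays open and was not tested, as age goes with table and with any harvest day, and Klf9 and Tsc22d3 moved by -2.61 h and -2.39 h, and an earlier clock phase with age stays open as a hypothesis, found and tested on the same data.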

How the results depend on the processing

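Array weights, the fit without the 2 aged libraries far from their groups (aged ZT16 replicate 3 and aged ZT8 replicate 1), the alternatives of list levels other than an estimated correlation and fry, and those of overlap and of clock amplitude and peak were chosen after seeing the data. Among results with an adjusted p under 0.05 in either fit, no named gene or list changed direction under any alternative run. The mast cell list, called in neither, was down by camera and up by fry. For gene rhythms a turn meant a peak moved by over 6 h. Directions of list profiles and of differences in rhythm were not compared. Which of the higher and lower counts was larger turned under several settings. For the mean level these were 1153 and 1216 at a filter of 50, 678 and 736 with cell marker covariates, and scaling to the total. It also turned at ZT4 and, under several settings, at ZT8. Examples at ZT8 are 220 and 156 with upper quartile scaling, 166 and 103 without the 2 far libraries and 350 and 311 by DESeq2. At ZT24 it turned at a filter of 50 (102 and 120), with array weights (313 and 343) and without the 2 far libraries (169 and 179). These near-even splits give no direction. Among named genes, leaving out 1 library left 3062 of 3062 level results on the same side of the threshold, and other settings 918 of 928. For rhythms these were 1045 of 1092 and 728 of 775 in young, 439 of 462 and 335 of 351 in aged cells and 474 of 504 and 150 of 179 for the difference. The 10 level results lost were all with cell marker covariates (C1qa, C1qb, Cd8a, Cd8b1, Eomes, Fcmr, Gpnmb, Hspd1, Hsph1 and Ndufc1). EdgeR and DESeq2 were not run on list profiles, which are averages and not counts.

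Genes rhythmic in young cells numbered 438, and 236 with no filter, 262 without the ZT0 libraries, 266 with a linear drift term, 248 at a fold of at least 1.5, 769 at an adjusted p under 0.1, 2082 at an unadjusted p under 0.05 and 737 by DESeq2. In aged cells they numbered 37, and 1083 at an unadjusted p and 91 by DESeq2. The difference in rhythm gave 0, and 5 and 7 at pseudocounts of 0.5 and 5, 3 with 7 time levels, 4 without the ZT0 libraries, 7 at an adjusted p under 0.1, 494 unadjusted, 9 adjusted over called genes, 1 with array weights, 4 by edgeR and 7 by DESeq2. ZT24 against ZT0 gave 2 in young and 1 in aged cells with no filter, and 1 in young cells by DESeq2. At ZT0 there were 59 at a filter of 50, 63 with no filter, 210 with array weights and 166 by DESeq2, where the main count was 96. Counts at other times moved from 163 to 268 by DESeq2 at ZT4, from 484 to 269 without the 2 far libraries at ZT8, from 251 to 403 with array weights at ZT12, from 128 to 73 without the 2 far libraries and 235 by DESeq2 at ZT16, from 200 to 126 with no filter and 517 with array weights at ZT20, and from 253 to 166 with no filter and 656 with array weights at ZT24. The mean level gave 2862, and 1414 with cell marker covariates. Lists called by camera were 13, and 0 with an estimated correlation, 30 by fry and 22 with no filter. Rhythmic list profiles were 8 in young and 2 in aged cells, and 14 and 4 at a filter of 50. The log2 amplitude ratio of the clock genes was -0.22, and past the threshold at -0.30 with no filter, -0.32 with upper quartile scaling and -0.32 without the ZT0 libraries. A permutation of ages within times, added after the result was seen, gave p = 0.0478 for that ratio on rescaled values, where the sign flip gave 0.162, against 0.152 for the planned sign flip on the separate tables. Settings that change the threshold or the number of genes or libraries change counts by construction, and for the others the cause was not tested.

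Each library left out in turn gave 0 to 5 genes for the difference in rhythm, 0 to 2 for ZT24 against ZT0 in young cells, 47 to 124 at ZT0, 73 to 205 at ZT4, 147 to 626 at ZT8, 103 to 298 at ZT12, 55 to 193 at ZT16, 33 to 227 at ZT20 and 32 to 452 at ZT24. The rhythmic genes were then 322 to 504 in young and 26 to 45 in aged cells, the level differences 2633 to 2994 and the clock shift -2.57 to -2.33 h. The replicate number does not pair the samples: 21 pairs of a young and an aged library of 1 number and time had correlations of -0.0878 to 0.0615, and 0 were over 0.1. With the replicate block 387 genes were rhythmic in young and 37 in aged cells, 0 differed in rhythm by limma and 2808 in level, so it moved no count by over 1.5 times. At these depths and 3 libraries per group, rhythms of a log2 amplitude of 0.25 were recovered for 17.9% of simulated genes in young and 19.4% in aged cells. Genes were simulated independently, so deviations that a library shares across genes are not counted in these shares.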

Other observations

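The tests of smaller rhythms in aged cells, of the proliferation genes with cell markers as covariates and of shuffles with the age means removed, and the weighing of both residual swaps together were chosen only after the results had been seen. In some gene groups not described so far single members differed between ages, and camera called none of these 4 lists. Of 28 genes of lysosomes 4 rose and 7 fell, also adjusted over the list alone, with Cd63 at a log2 fold of 1.08 ± 0.10 (SE; limma, adjusted p = 4.06e-11), and camera did not call the list (direction down, adjusted p = 0.427; median log2 fold -0.04, mean 0.01). Of 20 genes of oxidative stress 3 rose and 1 fell, also adjusted over the list alone, among them the iron storage gene Fth1, which rose by 0.50 ± 0.05 (camera adjusted p = 0.121). Of 13 genes of senescence and ageing 5 rose and 3 fell, also adjusted over the list alone. Spp1, which encodes osteopontin, rose by 2.68 ± 0.43 and Cdkn2a, a gene of cell cycle arrest, by 0.46 ± 0.12, while the lamin gene Lmnb1 stood at -0.79 ± 0.11, and camera did not call the list (adjusted p = 0.427). Of 16 eicosanoid genes 2 rose and 8 fell (2 and 9 adjusted over the list alone), with Ptges, a synthase of prostaglandin E, at 1.31 ± 0.12, and camera did not call the list (adjusted p = 0.0925).

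More genes were called rhythmic in young than in aged cells (438 and 37). A lower depth of the aged libraries is argued against: young reads thinned to the aged totals gave a median of 430.5 genes over 10 draws (418 to 452). A larger spread between aged libraries stays open: fitted young curves gave 448 genes with young residuals and 100 with aged residuals (72 to 123 with any aged library left out), above the 55.5 set before as the bound against it, while fitted aged curves gave 302 with young residuals. That bound does not decide, since swapped residuals carry no error of a fitted curve and each curve keeps the noise of its own libraries. Smaller rhythms in aged cells stay open: in genes picked on 2 young replicate numbers, clock genes left out, the rhythm in aged cells was 78.1% of that in the left-out young libraries on average (68.7%, 84.5% and 81.0%, exact permutation p = 0.114, 0.359 and 0.204), and these folds share libraries, so the gap in counts is not shown to be a loss of rhythm.

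Genes at a different mean level in aged cells may in part reflect a different share of B, T and mast cells, whose marker lists share no gene with the other lists and whose most abundant B cell marker, Ighm, stood at a log2 fold of 0.55. With scores of these markers as covariates 41.0% of the called genes (1174 of 2862) were still called, so more calls ended than stayed, which was the outcome written down beforehand for this explanation, and it stays open. The mast cell list was itself not called for level (camera, adjusted p = 0.997). Other marker lists that camera called at its preset correlation were not among the covariates. These were mesothelial cells or fibroblasts (median log2 fold 2.09), natural killer cells (1.51) and dendritic cells (-0.63). Shares of those cells were not tested. The median absolute log2 fold of the called genes went from 0.38 to 0.34 while the median SE went from 0.0921 to 0.132, and 96.2% kept their sign. These medians are over all 2862 genes, and why single calls ended was not tested. The B and T cell markers themselves rose with age, so a wider SE does not tell the explanations apart. For the proliferation genes the B, T and mast cell scores did not account for the fall. With them as covariates 22 of 24 were still lower, at a median log2 fold of -1.15. The list of monocyte-derived macrophages (median log2 fold -0.73) and the dendritic cell markers fell with age too and were not among the covariates. A different share of those cells stays open for the proliferation genes. Age itself and any batch that goes with it stay open, as untested.

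Other splits of the libraries were run for each count. Of 100 splits, 1, the real one, gave as many rhythmic genes in young cells (438, highest other 7) and in aged cells (37, highest other 1). The same held for level differences (2862, highest other 2). A share of 1 in 100, the smallest that 100 splits can give, argues against a random assignment of libraries. The shuffles treat libraries as separate samples, which the labels do not state, and cannot tell age from a batch that goes with it. For the difference in rhythm limma's real count was 0, so any split gives as many and the splits cannot decide. They were counted by limma adjusted p alone, beside the real 494 unadjusted, 4 by edgeR and 7 by DESeq2. The highest other split gave 808. Shuffling ages within times turns level differences between ages into time patterns, so that count points to a structure of the samples. With the age means removed the highest was 2 and 4 shuffles made any call. At single times 10 splits exist, too few for a share under 0.05. The real split stood alone, 1 of 10, at each time, with 96, 163, 484, 251, 128, 200 and 253 genes from ZT0 to ZT24 and 1, 0, 9, 0, 0, 0 and 68 for the highest other. For ZT24 against ZT0 the real count was 0 in each age, which any split matches, and the highest other was 0 as well.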
